A study of Homo sapiens with 2 samples.

How the data were processed

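Total RNA labelled as coming from cultured A549 cells, a human lung adenocarcinoma line, was marked with Cy3 and hybridised to 2 Agilent 1-colour expression arrays, 1 for cells labelled wild type and 1 for cells labelled PNPT1 knockout. Groups were taken from the submitters' source names. With 1 array per group there was no replicate spread, so no test between groups was run and no p-value was computed; the number of arrays limits the precision. Both arrays carried the same scan entry in their headers, so no scan batch separated the groups.

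The deposited scanner tables hold a background-subtracted and detrended intensity per spot, made with Agilent Feature Extraction 11.0.1.1 per the file headers; the submitters' processing notes name version 9.1 of the same program. Those tables also hold the raw median intensity of each spot and of its local background, and 0 or 1 flags for outlier, saturated and well-above-background spots, per the file headers. The deposited series-level table holds processed values of the same arrays on the log2 scale, read as such from the values themselves. Its columns had the same median, 4.07, and their Spearman correlation across probes was 0.998 and 0.999 with the scanner values of the matching array, against 0.927 for the other array. The way background was treated in that table is not given in the sources used here, so it served only as an alternative.

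Processed intensities were taken to log2, spots flagged as population or non-uniformity outliers were left out (480 on the array labelled wild type, 415 on the array labelled knockout), repeated spots of a probe were averaged, and each array's 75th percentile over non-control probes was subtracted. No non-control spot was saturated (0 on either array). A gene's value was the mean of its probes well above background on both arrays. A gene well above background on only 1 array received a bound in place of a value: its brightest probe there was set against the higher of the other array's lowest well-above-background signal (4.93 on the array labelled wild type, 6.52 on the array labelled knockout) and the probe's own signal on that array. Where that ratio lay under 1 no fold was given. Bounds were computed only from these processed intensities under 75th percentile scaling, so a bound is a lower limit under that setting alone.

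The scanner tables give RefSeq and other accessions but no gene symbols. Accessions were matched without version numbers to RefSeq genes of assembly GRCh38.p14. Of 34127 probes, 25771 received 1 symbol, 0 received several and 8356 received none; 79 probes of Y-linked genes and XIST were left out. The array grid follows the hg19 build per the file headers, so the reference served only for names and for the order of neighbouring genes, and no coordinate is printed.

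Differences are log2 values on the array labelled knockout minus those on the array labelled wild type. Genes named in the text follow a rule of size: PNPT1; the 12 genes with the highest and the 12 with the lowest difference among genes measured on both arrays, with a mean level at or above the 25th percentile, at least 2-fold in the same direction under 75th percentile scaling, normexp and quantile settings, with all measured probes of the same sign, and with a symbol other than a provisional one; the 5 largest bounds in each direction; and, for each gene list, the extreme members, members at least 2-fold apart where the list stood outside its random range, and members with a bound. Other genes are said to have been chosen after their values were seen.

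The 40 gene lists, the marker lists of 9 other cell types and of A549, the naming rule and the alternative settings were fixed before the data were examined. Each list with at least 5 measured members was described by the percentile of its median among 10000 random lists of the same size matched on mean level in 10 bins, with the central 95% of those medians as its random range; the standard error of a list median came from 1000 bootstrap draws of its members and describes members, not replicates. These percentiles describe these 2 arrays and are not p-values. Technical spread within an array came from probes spotted 10 times: 811 of 999 such probes had at least 8 usable spots and lay well above background on both arrays.

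The alternatives were normexp background correction with an offset of 50, quantile normalization, loess between arrays with a span of 0.3, median scaling, the 75th percentile over probes above background on both arrays, the authors' series-level values, no filter on dim probes, only probes above the median level, the brightest probe per gene, and outlier spots kept. Normexp had been planned on mean spot intensities; the tables used here have no such column, so it was run on median intensities, a choice made after the data had been seen. Median scaling and the 75th percentile over probes above background on both arrays only subtract a constant from each array. They repeat every list's percentile by construction, so they add no evidence to counts of alternative settings. The steps were tested on simulated data made from the array labelled wild type, over 16634 genes. Past 2-fold, 100 of 100 genes altered 8-fold and 100 of 100 altered by 1.5 on the log2 scale were recovered. Of 16411 unaltered genes 0 passed, and 0 of 38 unshifted lists left their random range. The simulated array held only noise scaled from the spread of repeated spots, with no variation between cultures. The simulation thus checked the steps and gives no error rate for the real arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 with limma 3.58.1 and version 1.17.8 of the data.table package were used.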

Results

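Expression was measured on 2 arrays, 1 labelled wild type A549 and 1 labelled PNPT1 knockout, to ask which transcripts differ in A549 lung adenocarcinoma cells without PNPT1. PNPT1 encodes polynucleotide phosphorylase, an exoribonuclease of mitochondria that works with the helicase SUPV3L1 in degrading mitochondrial RNA. Each array held 44495 spots, of which 43118 were not controls. Of the probes, 84.6% lay well above background on the array labelled wild type and 83.0% on the array labelled knockout, with median spot signals of 96.1 and 95.6. The median negative control read 1.09 and 1.45. There were no replicate arrays, so no value below carries a replicate error, and all differences describe these 2 arrays. Within an array, probes spotted 10 times had a median SD of 0.06 log2 units (labelled wild type) and 0.07 (labelled knockout), and the SD of a difference between single spots was 0.10 at the median and 0.34 at the 95th percentile. Among 3939 genes with several measured probes, the median SD between probes of a gene was 0.36.

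The PNPT1 transcript was not lower on the array labelled knockout. Its difference was 0.30 (log2, labelled knockout minus labelled wild type), with 0.29 and 0.31 at its probes. The median SD of 0.36 between probes of a gene is no measure of error between arrays, so no error is set beside this difference. Probe A_23_P154488 read 421 on the array labelled wild type and 454 on the array labelled knockout, and probe A_32_P76035 read 55.4 and 60.8. The position of the edit is not given in the sources used here, and a probe outside the edited part checks nothing. Because the targeted transcript did not show which array holds the knockout, the arrays are called by their labels throughout, and every direction below is between labels.

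Transcripts typical of A549 were mostly higher on the array labelled knockout than on the array labelled wild type. Of 14 measured members of the A549 marker list, 9 were at least 2-fold higher on the array labelled knockout and 2 at least 2-fold lower. The list median of 2.87 (bootstrap SE 2.16) was higher than the medians of all 10000 matched random lists, the central 95% of which ran from -0.60 to 0.48. The aldo-keto reductase AKR1B10 read 6.41 on the array labelled wild type and 35267 on the array labelled knockout, and its other probe, not well above background on the array labelled wild type, read 1.13 and 52992. The deubiquitinating enzyme UCHL1 differed by 8.64, the hydroxysteroid dehydrogenases AKR1C3 and AKR1C1 by 8.43 and 8.23, and the aldehyde dehydrogenases ALDH3A1 and ALDH1A1 by 7.91 and 5.53. The calcium-binding protein S100P (-3.70) and the stress cytokine GDF15 (-1.37) were lower. KRT18, TXNRD1 and CPS1 stayed within 2-fold. By its brightest probe, CPS1 read 10168 on the array labelled wild type and 8312 on the array labelled knockout.

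Transcripts of CDKN2A, CDKN2B and MTAP, neighbouring genes known to be deleted in A549 and chosen after the marker values were seen, went the opposite way with 5 of 6 probes. CDKN2A, which encodes the cell cycle inhibitor p16, read 45617 and 7259 with its probes on the array labelled wild type, against 4886 and 6.45 on the array labelled knockout, the last not well above background. CDKN2B was well above background only on the array labelled wild type, at 56.2, where it was at least 7.63-fold higher. For MTAP, an enzyme of methionine salvage, 1 probe read 1007 and 7.99, another 75.8 and 1.47, and the remaining probe 179 and 247.

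**Figure D1:**
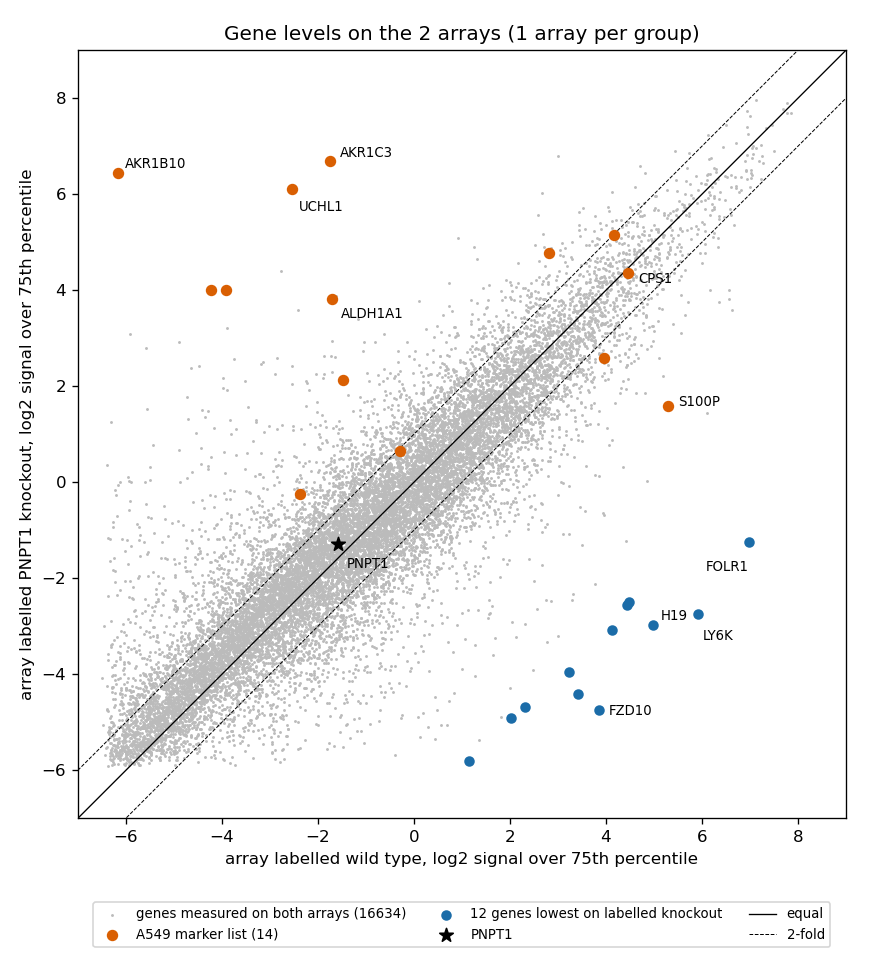
Level of each of 16634 genes on the array labelled wild type (x axis) and the array labelled knockout (y axis), both as log2 signal over the array's 75th percentile. Orange points are the 14 A549 markers, from AKR1B10 (difference 12.60) to S100P (-3.70), blue points the 12 genes lowest on the array labelled knockout by the naming rule, the star PNPT1 (0.30), and dashed lines mark 2-fold.

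Over the whole array, 2516 of 16634 genes measured on both arrays were at least 2-fold higher on the array labelled knockout and 2119 at least 2-fold lower, together 27.9% of the genes. At 4-fold the counts were 662 and 540, and at 16-fold 120 and 75. A further 432 genes were well above background only on the array labelled knockout and 643 only on the array labelled wild type, with bounds of at least 2-fold for 359 and 194 of them; 1964 genes were above background on neither. Across genes, which are not independent replicates, the arrays correlated with Pearson's r of 0.902 and Spearman's rho of 0.897. Under 75th percentile scaling the median gene differed by 0.13 and 54.3% of the genes past 2-fold were higher on the array labelled knockout; median scaling, under which the median gene differed by -0.01, gave 44.2%, with 2071 higher and 2618 lower.

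The genes highest on the array labelled knockout included 5 A549 markers, AKR1B10 (12.60) first. Besides AKR1B10, UCHL1, AKR1C3, AKR1C1 and ALDH3A1, the 12 highest held the secreted matrix phosphoprotein SPP1 (8.99), the vitamin D hydroxylase CYP24A1 (8.37), MALL (7.80), the secreted growth factor CLEC11A (7.57), the calcium-binding protein TESC (7.17), the monocyte chemokine CCL2 (7.09) and CDH1, or E-cadherin (7.07). SPP1 rested on signals of 7.66 and 3452, CDH1 on 9.80 and 1162. Under normexp and in the authors' series-level values SPP1 differed by 5.94 and 6.92, CYP24A1 by 5.54 and 6.47, and CLEC11A by 4.23 and 5.06. AKR1B10 and CDH1 differed by 9.17 and 4.32 under normexp. Among genes above background only on this array, the bounds were at least 4722-fold for AKR1B15, 599-fold for the glycosyltransferase GALNT14, 351-fold for the surface glycoprotein THY1, 282-fold for the gap junction protein GJA1 and 250-fold for PNMA8A. Bounds, here and elsewhere, were not recomputed under normexp or the other alternatives.

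The 12 genes lowest on the array labelled knockout were LY6K (-8.65), the Wnt receptor FZD10 (-8.61), the folate receptor FOLR1 (-8.23), the imprinted noncoding RNA H19 (-7.96), the guanine deaminase GDA (-7.83), the cytokine receptor subunit IL20RB (-7.20), the adaptor DOK7 (-7.17), CCN5 (-7.01), the cytoskeletal linker EPPK1 (-7.01), the phosphodiesterase PDE2A (-6.97), the keratin KRT17 (-6.95) and the prohormone convertase PCSK1 (-6.94). FOLR1 read 58140 on the array labelled wild type and 172 on the array labelled knockout. Under normexp and in the series-level values KRT17 differed by -3.94 and -4.87, and PCSK1 by -4.50 and -5.48. Genes above background only on the array labelled wild type had bounds of at least 539-fold for the metallothionein MT1M, 381-fold for FOLR3, 285-fold for the nucleotide transporter SLC17A9, 246-fold for the homeobox gene TLX3 and 236-fold for the cancer-testis gene MAGEA1.

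Among 40 fixed gene lists, 39 had enough measured members to be placed against random lists. The medians of 11 lay outside their random range, 7 of them higher and 4 lower on the array labelled knockout. If members were independent draws of genes matched on level, 1.95 of 39 lists would lie outside. Members of a list can vary together and some lists share genes, so setting 11 against 1.95 is no test. These stood beside the A549 marker list, which differed by 2.87 between the same arrays.

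Targets of NRF2, the transcription factor of the antioxidant response, were higher on the array labelled knockout. Of 33 measured members, 23 were at least 2-fold higher and 0 at least 2-fold lower, with a median of 1.80 (SE 0.56; 1.87 with bounds) above all random lists. Outside the A549 markers, the nuclear receptor NR0B1 (6.90) and the transporter ABCC2 (5.64) differed most, while NQO1, itself an A549 marker, differed by 3.60. The glutathione synthesis subunit GCLM (-0.81) and ferritin heavy chain FTH1 (-0.21) were the lowest members. CYP4F3 and CYP4F11 were above background only on the array labelled knockout, at least 15.3-fold and 5.95-fold higher. This list shares members with the A549 markers, whose median of 2.87 went the same way.

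Targets of the integrated stress response, through which ATF4 drives amino acid synthesis and transport, were lower on the array labelled knockout. Of 37 members, 25 were at least 2-fold lower and 1 at least 2-fold higher, with a median of -1.31 (SE 0.23) below all 10000 random lists. The hormone STC2 (-4.19), the stress regulator NUPR1 (-3.73) and the serine synthesis enzyme PHGDH (-3.12) were lowest, CTH, which makes cysteine, differed by -2.78 and ATF4 itself by -1.31. DDIT3 (-2.03), TRIB3 (-2.04) and asparagine synthetase ASNS (-1.71) were also lower. The lipoprotein receptor VLDLR (1.12) and ATF5 (0.68) were the highest members. The A549 marker list, which holds GDF15 in common with this list, had its median of 2.87 in the opposite direction.

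Interferon-stimulated genes were split. Of 45 measured, 11 were at least 2-fold higher on the array labelled knockout and 5 at least 2-fold lower, with a median of 0.48 (SE 0.15; 0.51 with bounds) at percentile 98.5 of the random lists. IFI35 (3.07), the RNA-sensing synthetase OAS1 (2.51), the ISG15-conjugating enzyme UBE2L6 (2.36) and SP110 (2.35) were highest, and SAMD9L and TRIM22 were at least 9.83-fold and 4.03-fold higher by bound. The antiviral membrane proteins IFITM1 (-5.26), BST2 (-4.31) and IFITM3 (-2.89) and the ubiquitin-like modifier ISG15 (-1.23) were lower. Under normexp the median was 0.32 and in the authors' series-level values 0.21. Cells on the same arrays differed by 2.87 in the A549 marker list.

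The sensors and ligands upstream of interferon lay inside their random ranges. For cytosolic RNA and DNA sensing, 4 of 23 members were at least 2-fold higher and 0 lower, with a median of 0.18 at percentile 66.7; the kinase IKBKE (2.15) was among the highest, TRIM25 (-0.90) and the double-stranded RNA sensor IFIH1 (-0.61) lowest, and the RNA sensor TLR3 was at least 1.76-fold higher by bound. Interferon ligands and receptors had 1 of 13 higher and 0 lower, with a median of 0.47 at percentile 86.2 (outside in 1 of 10 alternative settings, the series-level values), from the receptor IFNAR1 (-0.51) to the ligand IFNE (2.32). Interferon beta, IFNB1, named for its role after its value was seen, differed by 0.17.

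Genes of NF-kappaB signalling and its cytokines were higher on the array labelled knockout. Of 25 measured, 11 were at least 2-fold higher and 1 at least 2-fold lower, with a median of 0.79 (SE 0.26; 1.14 with bounds) at percentile 99.9, beside the A549 marker median of 2.87. The chemokines CCL2 (7.09), CXCL1 (5.65), CXCL8 (4.58) and CXCL5 (4.18) were highest and the cytokine IL6 (-1.57) lowest. Acute phase gene SAA2, the chemokine CCL20 and SAA1 were at least 19.5-fold, 13.4-fold and 6.77-fold higher by bound, and CSF3, CXCL6 and CSF2 at least 3.25-fold, 2.85-fold and 2.46-fold. Without a filter on dim probes the median was 1.17.

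Genes of MHC class I antigen presentation, which displays peptides at the cell surface, went both ways around a negative median. Of 21 members, 10 were at least 2-fold lower on the array labelled knockout and 4 at least 2-fold higher, with a median of -0.60 (SE 0.64) at percentile 0.47, while the A549 marker median was 2.87. HLA-F (-3.12), HLA-B (-2.74), HLA-G (-2.60), HLA-C (-2.46) and the light chain B2M (-2.45) were lowest, and the proteasome activators PSME1 (1.81) and PSME2 (1.38) and the peptidase ERAP2 (1.79) were highest. The list lay inside its random range under normexp (median -0.28, percentile 6.14) and with the brightest probe per gene (median -0.11, percentile 31.4). HLA genes are close in sequence, so a probe can read more than its own gene. HLA-B also closed a block of 50 neighbouring genes, starting at GABBR1, that was lower as a whole. Its median was -0.74, with 18 genes at least 2-fold lower and 3 higher. Random lists were matched on level and not on position, so the list's percentile does not separate the pathway from its chromosome neighbourhood.

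**Figure D2:**
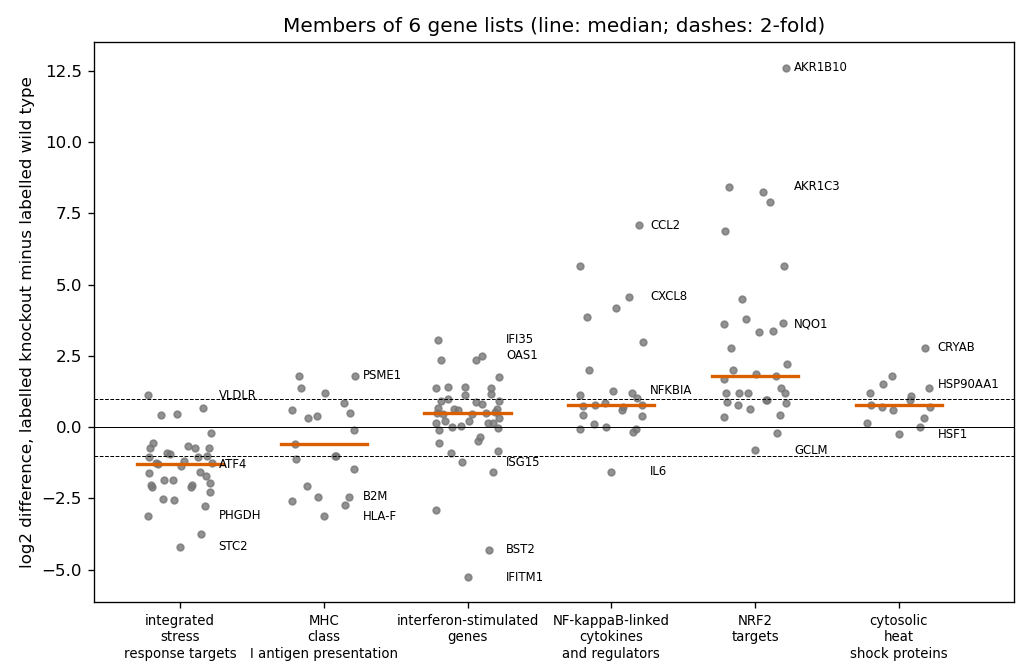
Each point is a gene measured on both arrays, placed by its log2 difference (labelled knockout minus labelled wild type, y axis) within 6 gene lists (x axis); orange lines are list medians and dashes mark 2-fold. Medians run from -1.31 for integrated stress response targets to 1.80 for NRF2 targets.

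Heat shock and proteasome genes were higher on the array labelled knockout and ribosomal protein genes lower, beside the A549 marker median of 2.87. Cytosolic heat shock proteins had 6 of 15 at least 2-fold higher on the array labelled knockout and 0 lower, with a median of 0.77 at percentile 99.8, with the small heat shock protein CRYAB (2.78) and HSPA1B (1.79) highest and HSPH1 at 1.39. Proteasome subunits had 9 of 31 higher and 1 lower, with a median of 0.40 at percentile 99.7; PSMD1 (1.87) and PSMB3 (1.69) were highest and PSMC3 (-1.10) lowest. Cytosolic ribosomal proteins had 9 of 74 at least 2-fold lower and 1 higher, with a median of -0.47 at percentile 0.01, from RPL37 (-1.59) to RPS16 (1.17). The ER unfolded protein response had 2 of 19 higher and 0 lower (median 0.31, percentile 91.4), and ribosome biogenesis 0 of 31 higher and 7 lower (median -0.29, percentile 13.6).

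Genes of the G1/S transition were lower on the array labelled knockout and replication-dependent histones higher, with the A549 marker median at 2.87. Of 36 G1/S and DNA replication genes, 10 were at least 2-fold lower and 2 higher, with a median of -0.46 at percentile 0.79; the replicative helicase subunit MCM2 (-1.81) and E2F2 (-1.78) were lowest and cyclin CCNE1 (1.67) highest. Of 35 histone genes, 4 were higher and 2 lower, with a median of 0.34 at percentile 98.7, which was inside the random range in 5 of 10 alternative settings. H1-5 (1.67) and H2AC20 (1.45) were the highest histones, H2AC8 (-1.19) and H4C11 (-1.10) the lowest, and H1-1 was at least 2.56-fold lower by bound. G2/M and mitosis genes had 1 of 36 higher and 3 lower (median -0.13, percentile 37.7).

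Targets of TGF-beta signalling were higher on the array labelled knockout, again with an A549 marker median of 2.87. Of 23, 10 were at least 2-fold higher and 4 at least 2-fold lower, with a median of 0.61 (SE 0.49; 0.80 with bounds) at percentile 99.4. The transcriptional regulator ID2 (4.54), the latent TGF-beta binding protein LTBP2 (2.95) and the signal transducer SMAD3 (2.77) were highest, CCN1 (-2.77) and LTBP1 (-1.28) lowest, and the ligand BMP4 was at least 8.79-fold higher by bound. Under loess between arrays the list was at percentile 97.3, inside its random range.

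Nuclear genes of the mitochondrion, the compartment of PNPT1, lay inside their random ranges. Mitochondrial RNA processing and decay had 1 of 25 at least 2-fold higher and 3 lower (median -0.34, percentile 8.29), with RMND1 at -1.83, the tRNA modifier MTO1 at -1.51 and FASTKD5 at 1.18. SUPV3L1, the helicase partner of PNPT1, named for its role after its value was seen, differed by -0.53. Complex I subunits had 3 of 37 higher and 4 lower (median 0.21, percentile 95.9), with NDUFB5 (-1.43) lowest and NDUFA3 (1.45) among the highest, and complexes II to V 3 of 38 in each direction (median 0.16, percentile 92.5). Mitochondrial ribosomal proteins had 4 of 75 higher and 9 lower (median -0.12, percentile 33.4), from MRPS25 (-2.59) to MRPL23 (2.84). Mitochondrial DNA replication and transcription had 0 of 19 higher and 4 lower (median -0.06, percentile 41.4), and its coactivator PPARGC1A was at least 19.4-fold lower by bound. Chaperones and proteases of the organelle had 0 of 16 higher and 3 lower (median 0.00, percentile 58.0), and mitochondrial dynamics and import 3 of 29 in each direction (median 0.04, percentile 66.5). For the 13 mitochondrially encoded genes 0 named probes were measured.

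Other RNA turnover and stress lists were also inside. RNA exosome and cytosolic decay genes had 1 of 27 higher and 6 lower (median -0.20, percentile 20.8), with the deadenylase subunit PAN2 (-2.24) and the exosome nuclease DIS3 (-1.94) lowest. Targets of p53 had 6 of 27 higher and 2 lower (median -0.01, mean 0.34, 0.09 with bounds, percentile 37.6), from GADD45A (-2.15) to EDA2R (2.80), and SPATA18 was at least 17.0-fold higher by bound. Cell death regulators had 3 of 27 higher and 6 lower (median 0.26, mean -0.13, percentile 85.8), with CASP4 (-3.24) and BIK (-3.23) lowest and the pore-forming GSDMD (1.66) highest. Autophagy and lysosome genes had 2 of 33 in each direction (median -0.13, percentile 33.2). Senescence-associated factors had 6 of 18 higher and 3 lower (median 0.26, percentile 81.8), with IGFBP4 (5.59) highest, and complement, coagulation and acute phase genes 7 of 18 higher and 3 lower (median 0.34, percentile 81.2; outside in 2 of 10 alternative settings), from the coagulation starter F3 (-3.41) to the complement protease C1S (2.81). Housekeeping reference genes had 0 of 20 higher and 5 lower (median -0.23, percentile 25.1).

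The metabolic and hypoxia lists lay inside their random ranges. Glycolysis had 4 of 24 higher and 7 lower (median 0.02, mean -0.33, percentile 58.5): hexokinase HK2 (-5.19) and the glucose transporter SLC2A3 (-3.65) were lowest, and the regulatory kinases PFKFB3 (4.36) and PDK4 (4.06) highest. Hypoxia-inducible genes had 1 of 22 higher and 8 lower (median -0.44, -0.24 with bounds, percentile 3.54; outside its range under normexp, at 2.27), with NDRG1 (-3.29) and VEGFA (-2.99) lowest and the carbonic anhydrase CA12 at least 90.7-fold higher by bound. Cholesterol biosynthesis had 7 of 23 higher and 2 lower (median 0.18, percentile 78.2; outside with the brightest probe per gene, at 99.7), with the sterol reductase TM7SF2 (1.54) highest. Fatty acid synthesis and oxidation had 4 of 23 higher and 1 lower (median 0.09, percentile 67.8), led by the desaturase FADS2 (3.37), and the tricarboxylic acid cycle 1 of 21 in each direction (median 0.01, mean -0.02, percentile 56.1).

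Epithelial and lineage genes went both ways. Among epithelial adhesion genes and keratins, 8 of 30 were higher on the array labelled knockout and 7 lower (median 0.17, percentile 70.0), with CDH1 (7.07) and the claudin CLDN3 (5.94) highest and CLDN4 (-3.99) and the adhesion molecule EPCAM (-3.46) lowest. With only probes above the median level that median was -0.60 at percentile 1.23, below the random range. Mesenchymal genes had 7 of 23 higher and 3 lower (median 0.17, percentile 74.3), with the repressor SNAI2 (-1.99) lowest, and the microfibril protein FBN1 was at least 23.2-fold lower by bound. Lung epithelial markers had 8 of 23 higher and 3 lower (median 0.45, percentile 92.5; outside its range in 5 of 10 alternative settings), from the lung lineage factor NKX2-1 (-2.68) to the endoderm factor FOXA2 (6.32). Wnt targets and stemness genes had 7 of 17 higher and 3 lower (median 0.52, percentile 96.2; outside in 4 of 10), with the Wnt inhibitor DKK1 at 4.55 and MYC at -2.17, and the pluripotency factor SOX2 at least 11.8-fold higher by bound.

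Markers of other cell types were measured on the same arrays. Neuronal and kidney-line markers had 5 of 5 members at least 2-fold higher on the array labelled knockout (median 1.80, percentile 99.9; outside in 9 of 10 alternative settings), with the tubulin TUBB3 at 2.99. T and NK cell markers had 1 of 11 higher and 0 lower (median 0.84, percentile 97.9), outside the random range in 5 of 10 alternative settings. Myeloid markers had 4 of 8 higher and 1 lower (median 0.72, percentile 95.7; outside in 1 of 10), B cell markers 0 of 5 in either direction (median 0.38, percentile 64.1) and endothelial markers 1 of 6 higher and 0 lower (median 0.59, percentile 83.3). With fewer than 5 measured members, only medians are given for fibroblasts (-0.86 over 4), hepatocytes (0.44 over 3), erythroid cells (1.02 over 4) and squamous keratinocytes (0.64 over 4), the last with KRT14 at least 126-fold lower by bound.

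**Figure D3:**
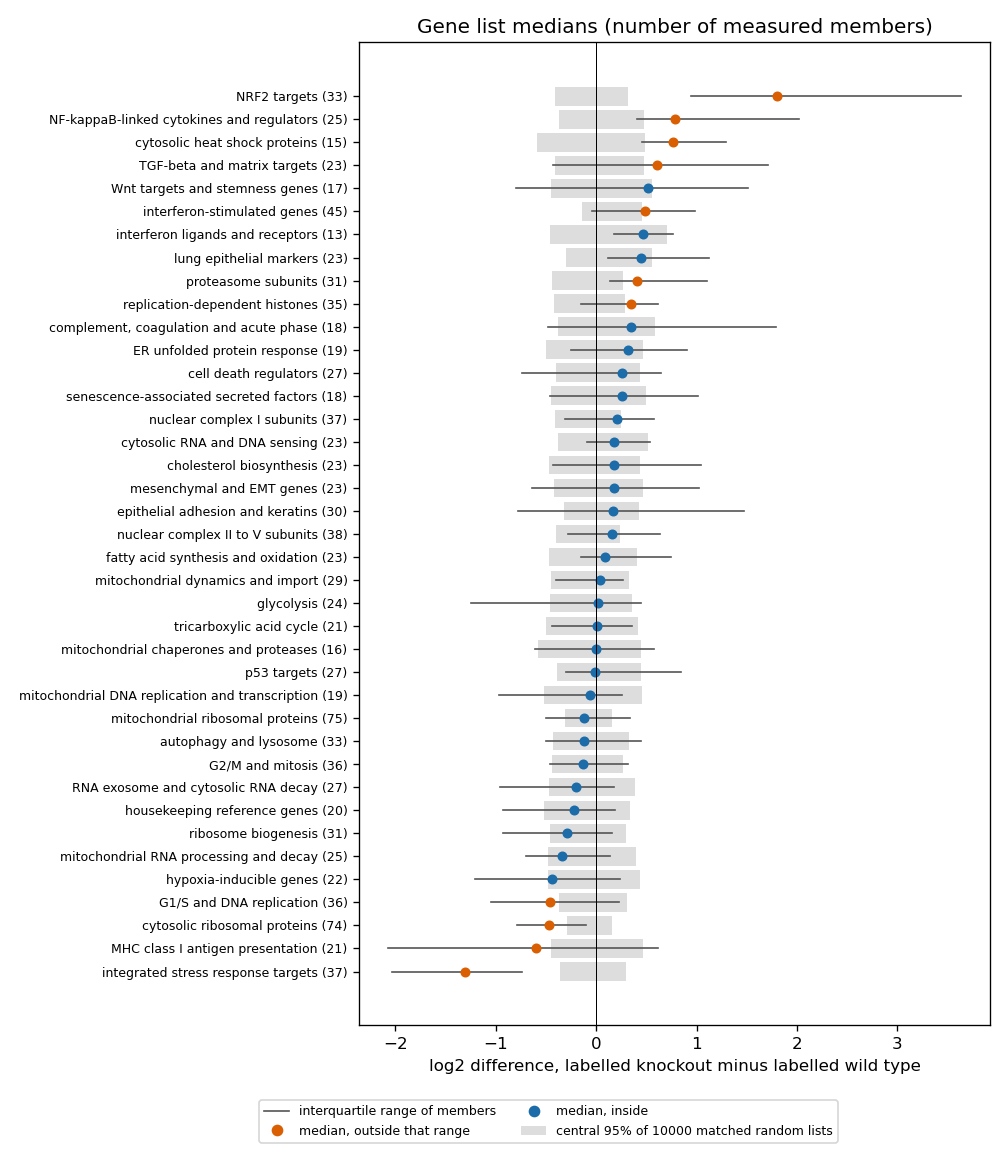
Median log2 difference (labelled knockout minus labelled wild type, x axis) of 39 gene lists (y axis, measured members in brackets), with the interquartile range of members as lines and the central 95% of 10000 matched random lists as grey bars. Orange medians, 11 in number, lie outside the grey bar.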

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

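The loess setting and the test on blocks of neighbouring genes were fixed in advance; the use of loess medians as tests, and all other tests in this part, were chosen after the results they bear on had been seen. Outside the named genes, 11 of 6079 probes with no gene name that were well above background on both arrays read at least 16-fold higher on the array labelled knockout.

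The A549 markers were mostly lower on the array labelled wild type, with a list median of 2.87 in favour of the array labelled knockout. RNA of A549 cells on the array labelled wild type is argued against by some probes of genes that A549 has lost. Of the probes of CDKN2A, CDKN2B and MTAP, 3 were silent on the array labelled knockout, which had the A549 markers. These 3 of 3 were well above background on the array labelled wild type, as were all 6 probes. The other 3 also read on the array labelled knockout, at 4886 (CDKN2A), 247 and 7.99 (MTAP). Signal of lost genes there is at odds with the premise unless these probes read other RNA, which was not tested. The argument therefore holds only if the 3 silent probes report the loss. A mixture with 1% or more of A549 RNA is argued against by the 6 markers at least 16-fold lower there, whose brightest probes kept a median of 0.207% of their signal: of all 10 probes of these markers 9 kept less than 1% (8 were measured, at 0.0161% to 2.17%, the highest from ALDH1A1, and 2 were under the floor, at 0.0101% or less), and scaling is argued against by the loess median of 2.81 (SE 2.12), above the random range's upper end of 0.49. RNA of different cell lines on the 2 arrays is a candidate explanation: it needs differences that cluster along chromosomes, and the SD of medians over 311 blocks of 50 neighbouring genes was 2.02 times the mean of 1000 shuffled orders (0.30 against 0.15, highest shuffle 0.17). Neighbours regulated together, or chromosome changes within a clone, could also give such blocks. Loss of PNPT1 as the only difference between cultures of A549 is argued against by the same 3 silent probes, on the same condition. Any part of PNPT1 loss in the gap was not separated.

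The PNPT1 transcript differed by 0.30 and was not lower on the array labelled knockout. An edit that leaves the transcript standing, or that lies away from both probes, may account for it. It cannot be told apart from a wrong label on either array, because the position of the edit is not given in the sources used here and each group has 1 array.

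Integrated stress response targets were lower and NRF2 targets higher on the array labelled knockout. Scaling or a trend with intensity is argued against, since under loess the medians were -1.23 (SE 0.22; random range down to -0.36) and 1.75 (random range up to 0.30). A difference between cell lines may account for both lists. For NRF2 targets, A549 is known for high NRF2 activity through mutated KEAP1. The 27 NRF2 targets outside the A549 markers kept a median of 1.38 (random range up to 0.37). Because 23 of all 33 measured NRF2 targets were at least 2-fold higher, that outcome was fixed beforehand and is no test. These points do not bear on the integrated stress response list, for which a difference between lines was not tested. An effect of PNPT1 loss predicts no value here that a difference between lines forbids, so these explanations cannot be told apart with 1 array per group.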

How the results depend on the processing

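Normexp on median intensities was chosen after the data had been seen, in place of normexp on mean intensities, which was not run; all other alternatives were fixed earlier. PNPT1, the 24 genes named as highest or lowest and the lists fixed in advance and outside their random range kept their sign under the alternatives that gave them a value (6 of the 24 had none with only brighter probes); under normexp and quantile the naming rule itself fixed this for the 24, and other named genes were not followed one by one. Among all genes past 2-fold 1 without the filter, 1 with only brighter probes and 4 with the brightest probe per gene passed 2-fold on the other side. The PNPT1 difference moved by less than the spread between probes in 10 of 10, list medians moved by less than 1 bootstrap SE in 384 cases and by more in 16, and the 24 genes moved by less than the spread between probes in 182 cases and by more in 52. Sizes of the 24 named differences (6.94 to 12.60) were 3.94 to 9.17 under normexp, nearer 0 in 24 of 24, and 4.87 to 11.91 in the series-level values, nearer 0 in 15 of 24, so the printed sizes of genes dim on 1 array depend on the processing. The count of genes at least 2-fold higher (2516) was 1326 under normexp, 1634 in the authors' series-level values and 1212 with only probes above the median level; the count of lower genes (2119) was 1372 under normexp and 1390 with only the brighter probes. All 1326 higher and 1359 of the 1372 lower genes under normexp also passed 2-fold under 75th percentile scaling. Normexp with an offset draws dim signals together by construction and the bright-probe setting holds 9148 genes in place of 16634; for the series-level values the cause was not tested. The interferon-stimulated median (0.48) was 0.32 under normexp and 0.21 in the series-level values, the integrated stress response median (-1.31) was -1.68 in the series-level values, and the NF-kappaB median (0.79) was 1.17 without a filter on dim probes; the cause was not tested. Lists outside their random range numbered 11 to 13 across alternatives, with 9 to 11 of the original 11 among them. Median scaling and the 75th percentile over probes above background on both arrays repeated the original 11 by construction. Those settings cannot change a list's percentile, yet they are included wherever alternatives are counted for a list or family. Signal over background limits genes near the floor, which have bounds only. Bounds were not recomputed under the alternatives, so their sizes can depend on the processing too. Leaving out either array was not possible with 1 per group. No paired analysis was possible because each group has 1 array and no test was run.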

Other observations

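Of the families below, the HOX test and the zinc finger, tubulin, protocadherin and collagen families were chosen before their values were seen, and the aminoacyl-tRNA synthetases and keratins after; the restriction to protein-coding genes was also chosen after. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, were lower on the array labelled knockout: 8 of 17 were at least 2-fold lower and 0 higher, with a median of -0.81 (percentile 0.25; -1.01 to -0.74 across alternatives). SARS1 (-2.51), QARS1 (-1.73) and CARS1 (-1.60) were lowest and IARS1 (0.29) highest. Of the 17, 4 were also counted in the integrated stress response list. That list named further synthetases by older symbols that matched no unique current symbol and were left out of it. The overlap as first fixed was therefore larger. Genes with ZNF symbols had 82 of 437 at least 2-fold lower and 38 higher, with a median of -0.25 below all random lists (-0.39 to -0.07 across alternatives); without pseudogenes, noncoding and readthrough transcripts, 78 of 414 zinc finger genes were lower and 32 higher (median -0.26). Of 14 families looked at, 5 lay outside their random range; the others of these were tubulins with gamma-tubulin complex components (median 0.56, outside in 7 of 10 alternatives), keratins (0.59, 9 of 10) and collagens (0.57, mean -0.08, 4 of 10), the last with a negative median in 1 of 10. With protein-coding genes only, tubulins lay inside (median 0.38, percentile 96.4), though outside in 4 of 10 alternatives. Protocadherins with all their transcripts lay inside (0.54, percentile 96.8), though outside in 6 of 10 alternatives. Protein-coding protocadherins lay outside (0.61, percentile 98.7), as in 10 of 10 alternatives.

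Differences ran together along chromosomes, by the gene order of RefSeq. In the lowest block of 50 neighbours, from PRKAR2A to TUSC2, 24 genes were at least 2-fold lower on the array labelled knockout and 1 higher (median -0.96), and in the highest, from ZBTB32 to ZNF793, 24 were higher and 0 lower (median 0.87).

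Cells of different origin may carry different HOX programmes, the genes that record position along the body axis. Of 35 HOX cluster genes seen on either array, 57.1% were at least 2-fold apart, bounds included, against 29.7% in matched random lists (percentile 99.9). HOXC10 (-4.03) and HOXA13 (-2.47) were lower on the array labelled knockout, HOXD11 (3.96) and HOXD10 (3.22) were higher, and HOXA11 was at least 19.1-fold lower by bound. A raised share is what a different HOX programme means, so the result describes the difference and does not explain it. Nor was it particular to HOX genes. Among collagens 44.7% were at least 2-fold apart, against 29.4% in matched random lists (percentile 97.6). Protocadherins came near, with 42.9% against 30.3% (percentile 96.9). The HOX result does not separate cell origin from loss of PNPT1.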
